A study of Homo sapiens with 12 samples.

How the data were processed

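Poly(A) RNA had been sequenced from 12 libraries of cultured human keratinocytes, 3 in each of 4 groups: normal human epidermal keratinocytes (NHEK) and the HaCaT line, each with a scrambled hairpin RNA (shSC) or a hairpin RNA against KMT2D (shKMT2D). The libraries were made with a strand-marking kit after poly(A) selection, per the labels' protocols. STAR, DESeq2 and the GRCh37 (hg19) genome build are named in the submitters' processing notes, without versions. The counting tool, the gene annotation and the read length are not given in the sources used here. The deposited table holds 26364 genes and 1 column per library, with 0 columns that belong to other samples. Its values are FPKM-type values from the authors, that is read counts divided by gene length and by a depth factor of the library. They were not whole numbers, and within a cell type each gene's deposited FPKM values were whole multiples of 1 step per gene times 1 factor per library. The design fixed before the data were examined had assumed normalized counts, so the values were first turned back into reads.

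For each gene the value of 1 read was searched from the ratios of its values across libraries. It was found for 19370 genes, while 5279 genes were at 0 in all 12 libraries and 1715 were above 0 in 1 library only or could not be solved. Of the values above 0 in solved genes, 99.97% lay within 0.02 of a whole read, and the genes left out held 0.00622% of the summed values. As a check, values were shuffled between genes of 1 cell type: 0% of 2000 such shuffled genes could be solved up to a multiple of 2000, against 82.9% of as many real genes. For 61.05% of 17827 genes, the value of 1 read times the exon length lay within 10% of the median, as length-scaled values give. For 96.15% of the 17025 genes solved alone in each cell type, the ratio of the steps lay within 1.5% of the common ratio. That ratio still varied by 0.721% between the 5th and 95th percentile and followed the number of exons per kilobase (Spearman rho −0.88 across 15213 genes), so the authors' length scaling differed slightly between the NHEK and the HaCaT columns. The search was tested on 3000 simulated genes, of which 2955 were given a value and 98.58% of those had every read recovered. A GENCODE annotation of GRCh38 was used only for exon lengths and names. Since this build is not the one named by the submitters, no coordinates are given.

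Reads in genes (M, mega-reads) came to 35.5, 24.5 and 12.2 M in NHEK shSC replicates 1 to 3 and to 23.1, 22.7 and 13.3 M in NHEK shKMT2D. They came to 19.1, 17.9 and 18.0 M in HaCaT shSC and to 17.15, 18.5 and 21.0 M in HaCaT shKMT2D. A normalized count is here the deposited value divided by the gene's value of 1 read, taken as its geometric mean over the 12 libraries, which keeps the authors' scaling between libraries. XIST, TSIX and Y-linked genes (22 in all) were left out. Reads shared between near-identical genes (KRT6A, KRT6B and KRT6C, the KRT14, KRT16 and KRT17 group, the SPRR, S100A and IFIT families) may have been split or dropped in counting, so their values are less certain.

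Differences were tested with limma 3.58.1 in R 4.3.3 on log2(normalized count + 1), with a trend in the variance and robust moderation, two-sided, for genes with a normalized count of 10 or more in at least 3 libraries of the comparison. Fold changes are on this log2(value + 1) scale, which understates the change of low genes. Adjusted p-values are from the Benjamini-Hochberg procedure with a threshold of 0.05. The comparisons were shKMT2D against shSC in NHEK and in HaCaT, the difference between these effects (HaCaT minus NHEK, all 12 libraries in 1 model), and HaCaT shSC against NHEK shSC. Titles give each shSC library a number that it shares with a shKMT2D library of the same cell type, which makes 3 pairs per cell type. In HaCaT this number has the form of a date, so its pairs may stand for 3 days of work, though the labels do not say what the numbers mean. The deviations of libraries from their group means correlated between libraries of the same number at 0.78, 0.677 and 0.785 in NHEK and at 0.223, 0.188 and 0.565 in HaCaT, across genes. Every value was above 0.1, the limit set for calling the numbers a pairing. That limit does not compare same with other numbers. In HaCaT, libraries of pairs 1 and 2 reached 0.38 with a library of another number, above their same-number values of 0.223 and 0.188. The pairing is therefore less certain in HaCaT, and with it the paired HaCaT and shared calls. Each comparison was therefore fitted both without the pair and with the pair as a block. The labels do not say whether the replicates are separate cultures, so p-values measure the spread between these libraries, which may be in part technical.

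Genes are named by a rule fixed before the data were examined. It takes KMT2D, then the 10 largest rises and the 10 largest falls per cell type among called genes with a mean normalized count of 50 or more and the same direction in all 3 pairs. It takes 5 per direction for the difference of effects and for the control comparison, without the pair condition, the 8 largest shared changes per direction, and the 4 members of each gene list with the smallest p. Where fewer than 5 genes were called, it takes the 10 with the smallest p. Features with clone or placeholder names were passed over, and a few genes that the rule takes are not reported here. The same rule was applied to the paired fits, a decision made after the fit without pairs had called 0 genes in NHEK. The 27 gene lists were also fixed beforehand, from textbook knowledge. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, where at least 5 members could be tested, and counts of called members are given over all genes tested and adjusted over the list alone.

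The fits were tested on simulated reads with 200 changed genes, drawn with the real means, depths and deviations between pairs and an assumed spread within pairs, so the shares below hold for that spread. In NHEK the fit without pairs recovered 0% of 1.5-fold, 1.49% of 2-fold and 53% of 4-fold changes, against 76.1%, 100% and 100% with the block (13580 genes). In HaCaT the fit without pairs recovered 8.96%, 79.1% and 97%, against 79.1%, 100% and 100% with the block (14018 genes). Of 2-fold differences between the effects, 0% were recovered without and 88.5% with the block (14805 genes), and 69% of 2-fold changes in the control comparison (14122 genes). Unchanged genes made up 18 of 202 calls in NHEK and 11 of 197 in HaCaT with the block, more than the share of 0.05 that the threshold allows, against 0 of 36 and 0 of 123 without it. For the difference between the effects 9 unchanged genes were called with the block and 0 without it, and 11 in the control comparison. A cell cycle list raised 1.5-fold was called by camera at the preset correlation in each cell type. In NHEK with the block, 1 list that had not been raised was called as well. With camera at an estimated correlation the adjusted p of the raised list was 0.992 in NHEK and 0.0211 in HaCaT, and 0.123 and 0.0507 with the block. The simulated spread within pairs was drawn for each gene alone. In the real data the estimated correlation was, for example, 0.794 for spinous genes in NHEK with the block. The simulation therefore cannot tell how many real lists the preset correlation calls wrongly.

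Alternatives fixed beforehand were pseudocounts of 0.5 and 5, no filter and a filter of 50, TMM factors computed on the normalized counts, quantile normalization, the pair as a block, 1 fit on all 12 libraries, moderation without the robust option, 2-fold calls only, and leaving out each library. In the control comparison, a gene with 0 reads in all libraries of a group was given as a bound against a floor of 3 reads over that group, which covers counting error only. Alternatives chosen after the data had been seen were the deposited values plus 1, voom on the recovered reads, a sign-flip test of KMT2D, also with the sign of HaCaT pair 3 turned, and the paired fits under these settings and without each pair. Count tests that had been planned were not run, since the deposited values are FPKM-type, for which only tests on log values were used, and voom took their place. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9 were used for the search of reads and the plots.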

Results

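Poly(A) RNA was sequenced from 12 libraries of human keratinocytes in 4 groups of 3. Normal human epidermal keratinocytes (NHEK) are primary cells of the skin, and HaCaT is an established keratinocyte line that became immortal in culture. In each, a hairpin RNA against KMT2D (shKMT2D) was set against a scrambled hairpin RNA (shSC). KMT2D is a histone methyltransferase that acts at enhancers, and the series asks, by its title, how it acts on enhancers of p63, the transcription factor of stratified epithelia. Libraries that share a title number were treated as a pair, 3 pairs per cell type. Reads in genes ran from 12.2 M to 35.5 M per NHEK library and from 17.15 M to 21.0 M per HaCaT library. The table held 0 mitochondrially encoded genes. Values below are normalized counts as mean ± SD (n = 3) or log2 fold changes with SE, and adjusted p-values are from limma.

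KMT2D RNA was lower with shKMT2D in all 6 pairs, by a modest amount and in HaCaT pair 3 within counting error. In NHEK it went from 2574 ± 767 to 1934 ± 625, and the paired libraries with shKMT2D held 71.4%, 77.7% and 75.7% of the shSC level in pairs 1 to 3. In HaCaT it went from 3890 ± 1552 to 2693 ± 607, at 58.3%, 67.0% and 98.6% of shSC. The HaCaT shSC library of pair 3 held 2105, against 4654 and 4912 in the other shSC libraries, so KMT2D hardly differed within that pair. The log2 fold change was −0.42 (SE 0.30, adjusted p = 1) in NHEK and −0.46 (SE 0.32, adjusted p = 0.622) in HaCaT, within the spread between libraries. With the pair as a block, KMT2D fell in NHEK (SE 0.10, adjusted p = 0.011), while in HaCaT the difference did not pass (SE 0.14, adjusted p = 0.143). The paired NHEK call was lost when any 1 pair was left out, at an adjusted p of 0.0817, 0.0609 and 0.0637 without pairs 1, 2 and 3, and with the deposited values plus 1 (0.0617). Exact permutation tests, two-sided, gave p = 0.4 in NHEK and p = 0.3 in HaCaT, where 3 against 3 cannot go below 0.1, and p = 0.13 over 400 arrangements within both cell types. An exact sign-flip test over the 6 pairs, chosen after the data were seen, gave p = 0.0312, the smallest it can give. This rests on the sign of HaCaT pair 3, whose 98.6% has 95% exact counting bounds of 92.8% and 105%. With that sign turned, the exact p was 0.0625. Among 16 other members of the KMT2 complexes and family, 0 rose and 0 fell in either cell type by the paired limma fit (0 and 0 adjusted over the list alone; camera adjusted p = 0.216 in NHEK and 0.13 in HaCaT). The paralog KMT2C stood at 0.23 (SE 0.11, adjusted p = 0.216) in NHEK and at 0.25 (SE 0.10, adjusted p = 0.211) in HaCaT.

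**Figure D1:**
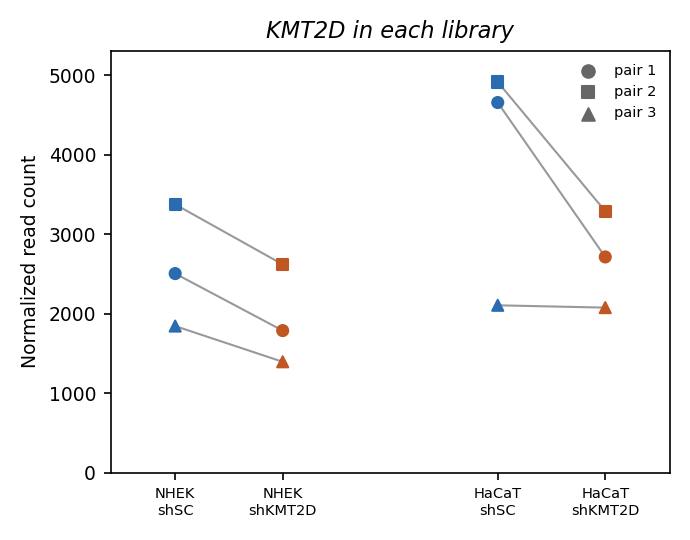
KMT2D normalized count in each library of NHEK and HaCaT, shSC in blue and shKMT2D in orange, with markers for pairs 1 to 3 and grey lines that join the libraries of a pair. All 6 lines go down from shSC to shKMT2D, least in HaCaT pair 3, where the level with shKMT2D was 98.6% of shSC.

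In NHEK, the comparison of shKMT2D with shSC asks what changed with the hairpin RNA against KMT2D in primary keratinocytes. The only knockdown condition in the labels is shKMT2D. Other effects of the hairpin RNA therefore cannot be told apart from those of less KMT2D, in NHEK or in HaCaT. Among the genes that rose were SPINK6, an inhibitor of skin proteases (15.1 ± 17.3 to 178 ± 118; log2 fold change 3.64, SE 0.61, paired adjusted p = 0.0221), the alarmin IL33 (2.29, adjusted p = 8.46e-07), and ZNF750, a transcription factor of terminal differentiation (37.0 ± 39.8 to 132 ± 98.5; 1.97, adjusted p = 0.00073). The cyclooxygenase gene PTGS2 rose from 1492 ± 210 to 5503 ± 2283 (1.81, SE 0.14, adjusted p = 2.03e-05). GBP6 (2.16), GLIPR1 (1.96), SERPINB3 (1.90), S100A8 (1.88), MAF (1.84) and VGLL3 (1.79) completed the 10 largest rises. MMP9, a secreted gelatinase, fell from 611 ± 359 to 68.5 ± 48.3 (−3.43, SE 0.52, adjusted p = 0.0496). The tight junction gene CLDN11 (−3.14), the cytokine gene TNF (−2.71), the Wnt ligand gene WNT10A (−2.19), SERTAD4 (−2.15), TRIM47 (−2.12), MMRN2 (−2.11), AEBP1 (−2.09), THY1 (−1.84) and the acute phase gene SAA1 (−1.80) also fell. With the pair as a block, 590 genes rose and 818 fell of 13429 tested, 131 and 116 of them at least 2-fold. Without the block, limma called 0 higher and 0 lower, with 630 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.249. Voom also called 0 higher and 0 lower, with 603 at an unadjusted p under 0.05. The paired total of 1408 was 329 without pair 2 and 771 without pair 3. The 10 smallest p without the block, none of which passed, were those of ABCC3 (−1.57, adjusted p = 0.249), IFIT1 (1.36, adjusted p = 0.778), and COL18A1, CTNNBIP1, FUT8, DCBLD1, PAK6, PTGS2, TDG and XYLT2 (adjusted p = 0.826 each).

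Differentiation lists were called higher in NHEK with shKMT2D. Unless stated otherwise, the calls and adjusted p-values here are from the fits with the block, as limma without it called 0 genes in NHEK. Of 13 genes of the spinous layer, the first differentiated layer of the epidermis, 2 rose and 0 fell (5 and 0 adjusted over the list alone), with a median log2 fold change of 0.95. The list was called by camera (adjusted p = 1.09e-08; adjusted p = 0.45 with an estimated correlation). DSG1, a desmosomal cadherin of differentiated layers, rose by 1.71 (SE 0.31, adjusted p = 0.0213) and CDKN1C by 1.09 (adjusted p = 0.0237), while KRT10 stood at 1.40 (adjusted p = 0.0807) and KRTDAP at 1.75 (adjusted p = 0.0927). Of 30 genes of the cornified envelope and granular layer, 4 rose and 1 fell (13 and 1 adjusted over the list alone), with a median of 0.81 (camera adjusted p = 1.18e-07; adjusted p = 0.496 with an estimated correlation). SCEL (1.55), TGM1, which cross-links the envelope (1.27), and CRCT1 (1.35) rose, and the protease gene KLK5 fell (−0.50). Of 18 differentiation transcription factors, 7 rose and 1 fell (9 and 3 adjusted over the list alone; median 0.34, camera adjusted p = 0.000236; adjusted p = 0.45 with an estimated correlation), among them GRHL1 (1.24), GRHL3 (1.12), KLF4 (0.75) and ZNF750. Of 26 desmosome and junction genes, 8 rose and 0 fell (11 and 1 adjusted over the list alone; median 0.27, camera adjusted p = 0.000161; adjusted p = 0.44 with an estimated correlation), with DSG3 at 0.83, DSC3 at 0.49, GJA1 at 0.46 and DSC2 at 0.42. With the block these 4 lists stayed called without any 1 pair, though the spinous median was 0.97, 0.17 and 2.04 in pairs 1 to 3. Without the block all 4 lost their call without NHEK shKMT2D replicate 1, the cornified list also without NHEK shSC replicate 3, and the desmosome list also without NHEK shSC replicate 2 or NHEK shSC replicate 3. The adjusted p went up to 0.0849 for spinous, 0.486 for cornified, 0.225 for transcription factor and 0.935 for desmosome genes.

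The lists of p63 targets and of the basal layer did not pass in NHEK, with or without the block. Without the block limma called 0 genes, and camera gave adjusted p = 0.442 for p63 targets, 0.161 for basal markers and 0.14 for hemidesmosome genes. The counts and values that follow are with the block. In the list of 22 genes that holds p63 and its targets, 6 rose and 3 fell (8 and 4 adjusted over the list alone; median 0.09, camera adjusted p = 0.134). SATB1 (0.90), KLF4 and ZNF750 rose, while JAG2 (−0.55) and the integrin gene ITGA3 (−0.32) fell. Of 14 basal markers, 0 rose and 2 fell (0 and 4 adjusted over the list alone; median −0.12, camera adjusted p = 0.105), namely DLK2 (−0.59) and ITGB4 (−0.35). Of 17 hemidesmosome and basement membrane adhesion genes, 0 rose and 2 fell, ITGB4 and ITGA3 (0 and 3 adjusted over the list alone; median −0.09, camera adjusted p = 0.0912).

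With the block, cell cycle genes fell and interferon response genes rose in NHEK with shKMT2D. Of 40 cell cycle genes, 0 rose and 22 fell (0 and 32 adjusted over the list alone), 39 had a negative fold change, and the median was −0.37 (camera adjusted p = 3.52e-16; adjusted p = 0.44 with an estimated correlation). MYBL2 fell by 1.11 (SE 0.11, adjusted p = 1.09e-05), FOXM1 by 0.67, BIRC5 by 0.61, and MKI67, the gene of the proliferation marker Ki-67, by 0.53 (adjusted p = 0.00218). Of 27 interferon response genes, 18 rose and 0 fell (21 and 1 adjusted over the list alone), with a median of 0.50 (camera adjusted p = 5.73e-16; adjusted p = 0.44 with an estimated correlation). IFIT1 went from 1638 ± 183 to 4227 ± 731 (1.36, SE 0.10, adjusted p = 2.24e-07), and ISG15 (1.37) and RSAD2 (1.18), as well as IFI44L, rose with it. Of 22 p53 targets, 6 rose and 0 fell (6 and 1 adjusted over the list alone; median 0.11, camera adjusted p = 0.0101; adjusted p = 0.44 with an estimated correlation), with SESN1 at 0.77, TIGAR at 0.51, ZMAT3 at 0.46 and SESN2 at 0.46. Of 23 hypoxia and glycolysis genes, 6 rose and 2 fell (7 and 2 adjusted over the list alone; median 0.19, camera adjusted p = 0.0101; adjusted p = 0.457 with an estimated correlation), with the glucose transporter gene SLC2A1 at 0.81, NDRG1 at 0.79, ADM at 0.75 and PDK1 at 0.58. Of 24 cholesterol synthesis genes, 0 rose and 4 fell (0 and 6 adjusted over the list alone; median −0.17, camera adjusted p = 0.00601; adjusted p = 0.44 with an estimated correlation), among them HMGCS1 (−0.59), MVD (−0.42) and LSS (−0.34). Of 24 genes of the unfolded protein and ATF4 response, 3 rose and 3 fell (3 and 3 adjusted over the list alone; median −0.18, camera adjusted p = 0.0102; adjusted p = 0.694 with an estimated correlation), VLDLR rising (0.60) and PDIA4 (−0.53), SLC7A5 (−0.51) and HSP90B1 (−0.49) falling. The p53 and hypoxia calls were lost without pair 1 (adjusted p = 0.121 and 0.126) and the unfolded protein call without pair 2 (0.233). Without the block camera called 11 of 23 lists against 10 with it. The Wnt list was called without it (adjusted p = 0.0433; adjusted p = 0.392 with an estimated correlation) and not with it. The cell cycle call without the block was lost without NHEK shSC replicate 3, NHEK shKMT2D replicate 1 or NHEK shKMT2D replicate 2 (adjusted p up to 0.505). Without the block it called 1 list without NHEK shKMT2D replicate 1 and 7 without NHEK shSC replicate 3.

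In the fit with the block, which is used for both cell types here, some markers of other cell types also moved in NHEK. Of 6 fibroblast markers, 2 rose and 1 fell (2 and 1 adjusted over the list alone; median 0.26, camera adjusted p = 0.707). DCN rose from 11.8 ± 1.40 to 40.1 ± 14.6 (1.63) and FBN1 from 481 ± 309 to 705 ± 329 (0.64), while THY1 fell from 948 ± 736 to 278 ± 259. The lists of melanocyte, immune and endothelial markers had 2, 2 and 1 members above the filter, too few for a list test. MITF rose (0.82), while the immune marker CD74 (−0.56) and the endothelial marker ROBO4 (−1.47) fell. In HaCaT, 3 fibroblast, 2 melanocyte, 1 immune and 1 endothelial markers could be tested. Of the fibroblast markers 0 rose and 1 fell, FBN1 at −0.83 (0 and 3 adjusted over the list alone), and of the other 4 markers 0 rose and 0 fell (0 and 1 over their lists alone, the immune marker).

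In HaCaT, the comparison asks the same of an immortal keratinocyte line. Among the genes that rose without the block, CALML5, a calcium-binding protein of differentiating keratinocytes, went from 10.8 ± 3.68 to 100 ± 62.8 (2.97, SE 0.46, adjusted p = 0.042) and KRT16, a stress keratin, rose by 1.81 (adjusted p = 0.0383). SP8 (1.81), TAS1R1 (1.77), ZNF711 (1.40), DCBLD1 (1.40), the ephrin receptor gene EPHA4 (1.34), TNRC6C (1.23), SCEL (1.15) and GDPD5 (1.03) made up the rest of the 10 largest. Falls included LOXL1, a lysyl oxidase that cross-links elastin, from 1215 ± 122 to 366 ± 12.9 (−1.73, SE 0.11, adjusted p = 0.00209), the complement gene C3, from 610 ± 106 to 134 ± 39.5 (−2.20, SE 0.22, adjusted p = 0.00971), and the collagen gene COL8A1 (−2.37, adjusted p = 0.0275). TNFAIP2 (−2.12), LRG1 (−2.10), APCDD1L (−2.05), SEMA6B (−1.93), TSPAN1 (−1.84), TMC8 (−1.77) and GPSM3 (−1.64) also fell. In total, 14 genes rose and 64 fell of 13947, and voom called 5 and 56. With the block, 141 rose and 344 fell. This added to the largest rises SPRR2E (3.46), PI3 (3.35), SPRR1A (3.03), KRT6C (2.80), ROS1 (2.53), SPRR1B (2.32) and OGDHL (2.06), and to the falls PTAFR (−2.19), BLNK (−2.07), RAB17 (−1.87) and HEPHL1 (−1.87). Reads of the SPRR genes, KRT6C and KRT16 can be shared with near-identical genes. The total of 78 was 6, 1 and 19 without HaCaT shSC replicates 1, 2 and 3, and 12, 20 and 22 without HaCaT shKMT2D replicates 1, 2 and 3. The paired total of 485 was 1035 without pair 2 and 59 without pair 3. In pair 3, on which the calls leaned most, KMT2D stood at 98.6% of shSC. Fold changes of pair 3 correlated with those of pairs 1 and 2 at r = 0.482 and 0.449 across genes. Those of pairs 1 and 2 correlated with each other at 0.231. The paired HaCaT calls thus cannot be tied to the size of the fall in KMT2D.

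Spinous and cornified lists were called higher in HaCaT too, but not once genes of low level were left out. With the block, 4 of 11 spinous genes rose and 0 fell (6 and 0 adjusted over the list alone), with a median of 0.84 (camera adjusted p = 0.00126; adjusted p = 0.521 with an estimated correlation). DSG1 rose from 2.57 ± 2.82 to 53.9 ± 43.7 (3.98, SE 0.51, adjusted p = 0.0116), KRTDAP by 3.42 and SBSN by 2.33. Of 20 cornified envelope genes, 6 rose and 0 fell (8 and 1 adjusted over the list alone; median 0.49, camera adjusted p = 0.00415; adjusted p = 0.521 with an estimated correlation). Of 20 differentiation transcription factors, 5 rose and 0 fell (7 and 0 adjusted over the list alone; median 0.44, camera adjusted p = 0.0251; adjusted p = 0.521 with an estimated correlation), among them ZNF750 (2.05), OVOL1 (0.78) and KLF4 (0.74). Desmosome genes, of which 2 of 26 rose and 0 fell (2 and 0 adjusted over the list alone; median 0.09), did not pass as a list (camera adjusted p = 0.0955), nor did 22 p63 targets (2 rose and 0 fell, 5 and 0 adjusted over the list alone; median 0.10, adjusted p = 0.13). Neither did 14 basal markers (0 rose and 0 fell, 0 and 0 adjusted over the list alone; median 0.08, adjusted p = 0.619) nor 17 hemidesmosome genes (0 and 0, and 0 and 0 adjusted over the list alone; median −0.08, adjusted p = 0.359). The spinous and cornified calls were lost without pair 1 (adjusted p = 0.118 and 0.24), and that of the transcription factors without pair 1 or pair 2 (adjusted p up to 0.0848) and without the block (0.19). With a filter of 50 normalized counts, 6 spinous genes (median 0.50, adjusted p = 0.0987), 13 cornified genes (−0.01, 0.214) and 15 transcription factors (0.13, 0.214) were left, and none of the 3 lists was called. Without the block, the spinous and cornified calls were lost at that filter as well (0.0871 and 0.369). They were also lost without HaCaT shSC replicate 1, HaCaT shKMT2D replicate 2 or HaCaT shKMT2D replicate 3 (adjusted p up to 0.0902 and 0.144).

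In HaCaT, the cell cycle and interferon lists were called against their direction in NHEK at the preset correlation, with few genes passing alone. With the block, of 40 cell cycle genes, 2 rose and 0 fell (10 and 0 adjusted over the list alone), 37 had a positive fold change, and the median was 0.20 (camera adjusted p = 6.15e-09; adjusted p = 0.568 with an estimated correlation). KIF20A (0.48) and E2F1 (0.40) rose, and MYBL2 stood at 0.45 (adjusted p = 0.0538). Of 23 interferon response genes, 0 rose and 7 fell (1 and 11 adjusted over the list alone; median −0.42, camera adjusted p = 0.000795; adjusted p = 0.521 with an estimated correlation). The list was mixed, with 15 negative and 8 positive fold changes, whereas in NHEK 26 of 27 were positive. OAS2 (−1.29), IFIT2 (−1.27), OASL (−1.22), OAS1 (−0.97) and IFIT1 (−0.87) fell. Fry called neither list (adjusted p = 0.2 each). Without the block limma called 0 genes of either, and the interferon call was lost without HaCaT shSC replicate 3 (adjusted p = 0.0802). The unfolded protein list was called lower, with 0 of 24 genes rising and XBP1 falling by 0.42 (0 and 3 adjusted over the list alone; median −0.17, camera adjusted p = 0.00691; adjusted p = 0.568 with an estimated correlation), and lost its call without pair 3 (adjusted p = 0.0772). The Notch list was called higher with the block (1 of 15 rose, HES1 at 0.47, and 0 fell, 1 and 0 adjusted over the list alone; median 0.20, camera adjusted p = 0.0132; adjusted p = 0.521 with an estimated correlation), but not without it (0.0939) or without pair 1 (0.0804). No call was made for 24 cholesterol (0 rose and 0 fell, 0 and 0 adjusted over the list alone; median −0.02, camera adjusted p = 0.955), 23 p53 (0 and 0, and 0 and 2 adjusted over the list alone; median −0.04, adjusted p = 0.312) and 23 hypoxia genes (0 and 1, and 0 and 3 adjusted over the list alone; median 0.00, adjusted p = 0.508). Camera called 7 of 22 lists with the block and 5 without it, with 13 left without pair 2 and 4 without pair 1. Without the block, 3 were called without HaCaT shSC replicate 1 and 2 without HaCaT shKMT2D replicate 3.

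**Figure D2:**
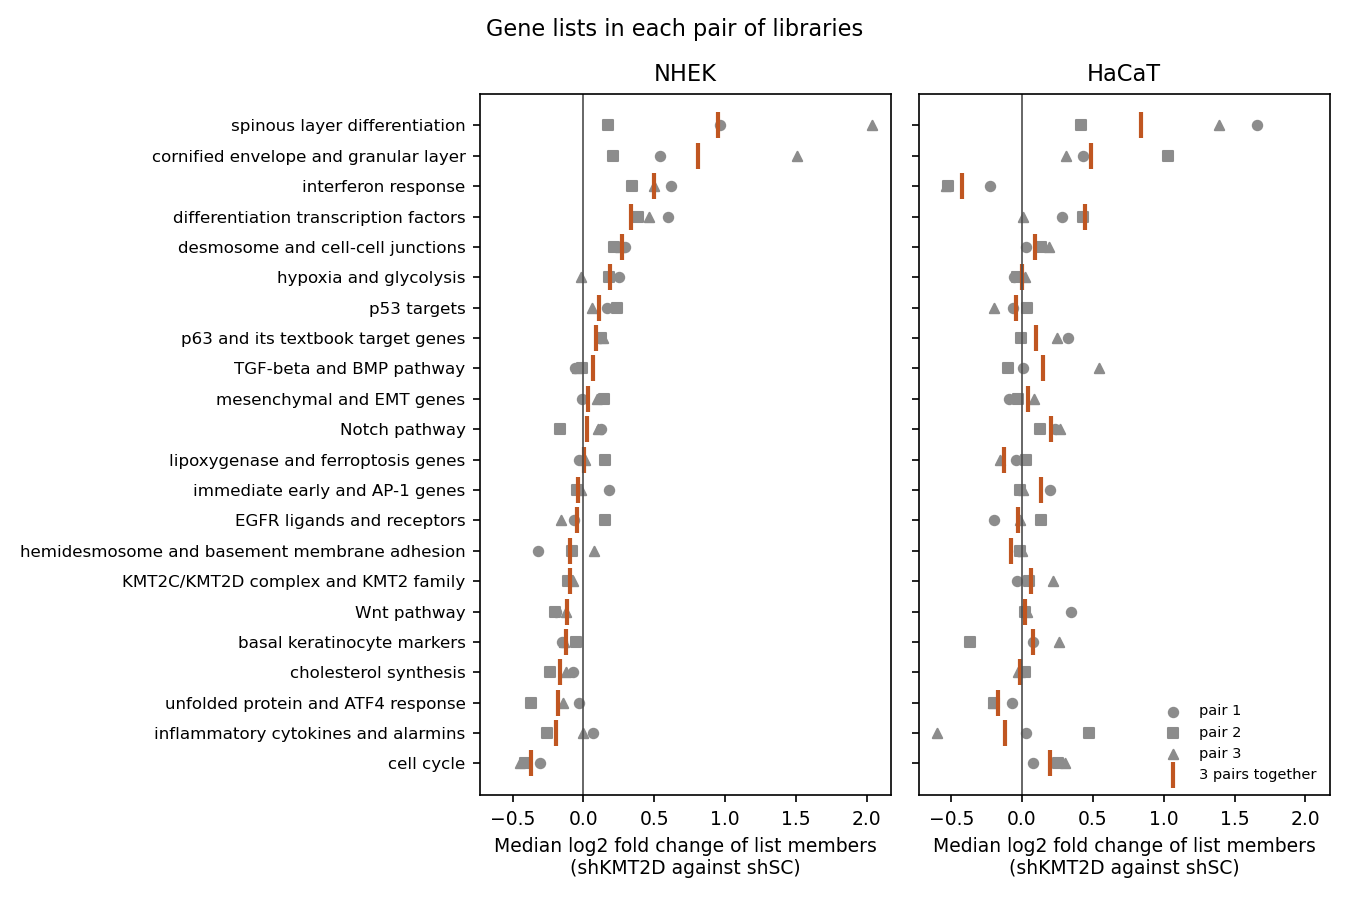
Median log2 fold change (shKMT2D against shSC) of each gene list in NHEK and in HaCaT, with grey markers for pairs 1 to 3 and an orange bar for the 3 pairs together. The interferon medians were 0.62, 0.35 and 0.50 in the NHEK pairs and −0.23, −0.52 and −0.54 in the HaCaT pairs.

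Changes shared by NHEK and HaCaT were set side by side to ask which effects of shKMT2D did not depend on the cell type. The differentiation genes ZNF750 and DSG1 and the keratin gene KRT6C rose in both, by 1.97 and 2.05, 1.71 and 3.98, and 1.78 and 2.80 in NHEK and HaCaT. Shared genes were named without a lower limit on the mean count, and some were low. In HaCaT shSC replicates 1 to 3, ZNF750 held 1.03, 10.1 and 7.40 and DSG1 0, 5.59 and 2.12. LRG1, named below, held 3.41, 11.4 and 7.13 in NHEK shKMT2D. ROS1 (2.03 and 2.53), OGDHL (1.72 and 2.06), EPHA4 (1.71 and 1.34), CD86 (1.29 and 1.62) and DCBLD1 (1.18 and 1.40) rose as well. LOXL2, a lysyl oxidase of the matrix, fell in both (−1.47 and −1.49), as did NTSR1 (−1.45 and −1.48), LRG1 (−1.44 and −2.10), PREX1 (−1.41 and −1.25), TNFAIP2 (−1.25 and −2.12), APCDD1L (−1.23 and −2.05), C3 (−1.19 and −2.20) and PTAFR (−1.10 and −2.19). Of 12756 genes tested in both, the paired fits called 37 higher in both, where 5.28 would be shared by independent lists (Fisher's exact test across genes, p = 1.07e-21). They called 82 lower in both, where 19.7 would be (Fisher's exact test, p = 7.59e-30). The test looked only for an excess and takes genes as independent, so its p-values do not measure the spread between libraries. By the same exact test, another 21 rose in NHEK and fell in HaCaT (13.4 by independence, p = 0.0282), and 5 fell in NHEK and rose in HaCaT (7.76, p = 0.894). Fold changes correlated at Pearson r = 0.281 and Spearman rho = 0.185 across genes, which are not independent replicates, and 55.7% of genes had the same sign. Without the block 0 genes were shared, since limma called 0 in NHEK (630 at an unadjusted p under 0.05, and 0 by voom). The paired total of 119 was 46 without NHEK pair 2, 207 without HaCaT pair 2 and 26 without HaCaT pair 3.

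**Figure D3:**
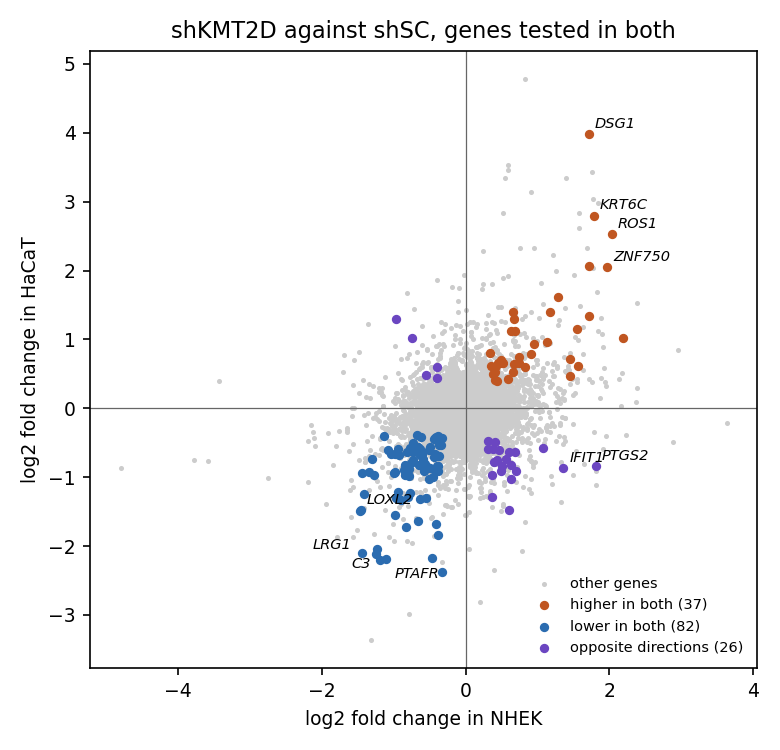
Log2 fold change with shKMT2D in HaCaT (vertical axis) against NHEK (horizontal axis) for each gene tested in both, with genes called by the paired fits in both cell types in colour. Orange marks the 37 genes higher in both, blue the 82 lower in both, and purple the 26 called in opposite directions.

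**Figure D4:**
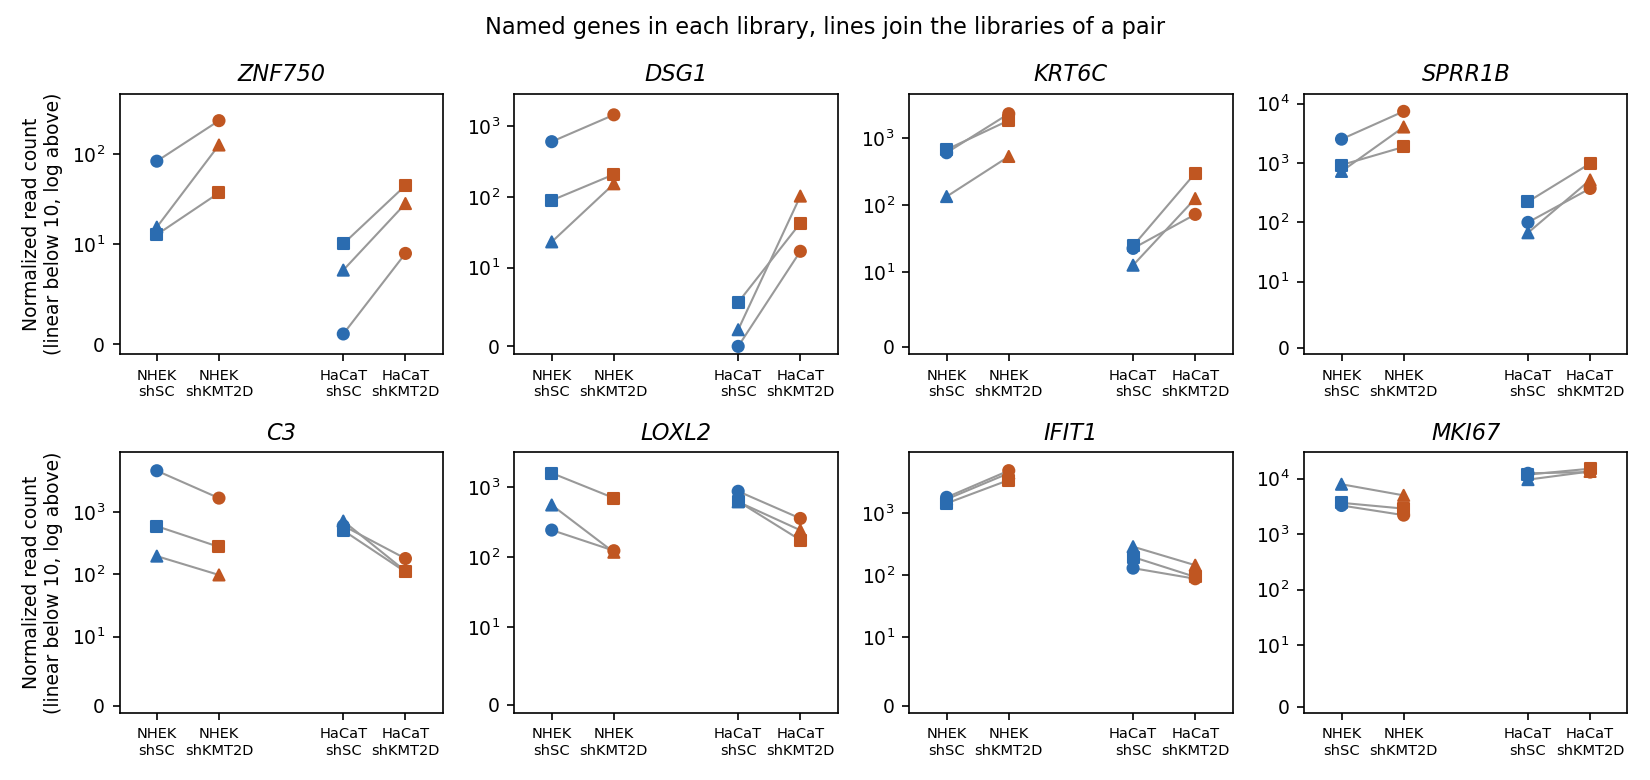
Normalized counts of 8 genes in each library of NHEK and HaCaT, shSC in blue and shKMT2D in orange, on an axis that is linear below 10 and logarithmic above. ZNF750, DSG1 and KRT6C were higher and LOXL2 lower with shKMT2D in both cell types, while IFIT1 rose in NHEK and fell in HaCaT.

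The difference between the effects (HaCaT minus NHEK) asks where the response depended on the cell type, and 2 genes passed without the block. TM9SF4, a membrane protein of the endosomal pathway, went from 3884 ± 185 to 1603 ± 87.2 in HaCaT and from 2180 to 2238 in NHEK (difference −1.32, adjusted p = 0.0165). ABCC3, an export pump for organic anions, went from 1804 ± 224 to 604 ± 51.0 in NHEK and from 2358 to 2186 in HaCaT (difference 1.46, adjusted p = 0.0165). Next by p, without passing, came MECOM (−1.30, adjusted p = 0.275), COMMD9 (adjusted p = 0.278), LMLN (−1.60, adjusted p = 0.297), SLC2A3, IFIT1, VAMP3, YWHAH and DUSP7. With the block 202 genes had a higher and 224 a lower effect in HaCaT of 14701. MMP9 (3.83), CLDN11 (3.30), PMP22 (2.27), HTRA1 (2.26) and CNTNAP2 (2.23) led one way. The other way went ALOX15B (−2.95), MYO3B (−2.79), PTGS2 (−2.65), GPX3 (−2.38) and GLIPR1 (−2.35). CLDN11, MMP9 and GPX3 had mean counts of 0.352, 8.26 and 2.83 in HaCaT shSC. Cell cycle genes separated the cell types, with a median difference of 0.54 that was positive in 40 of 40 genes (camera adjusted p = 8.81e-30; adjusted p = 0.159 with an estimated correlation). Of these, 19 passed upward and 0 downward (37 and 0 adjusted over the list alone), such as MYBL2 (1.57), KIF20A (1.02) and BIRC5 (0.91). Of 27 interferon genes, 0 passed upward and 14 downward (0 and 17 adjusted over the list alone; median −0.96, camera adjusted p = 9.55e-16; adjusted p = 0.159 with an estimated correlation), such as IFIT1 (−2.23, adjusted p = 9.97e-05), ISG15 (−1.79), IFIT3 (−1.35) and OAS1 (−1.34). Genes of the KMT2 complexes and family lay higher with the block (0 up and 0 down of 16, 1 and 0 adjusted over the list alone; median 0.17, camera adjusted p = 0.0221; adjusted p = 0.415 with an estimated correlation) and were not called without it (0.0555), nor with it when HaCaT pair 2 or HaCaT pair 3 was left out (adjusted p up to 0.143). For the spinous, cornified, transcription factor and desmosome lists the difference did not pass (camera adjusted p = 0.691, 0.612, 0.691 and 0.545 with the block). With fry, which tests each list by itself, cell cycle and interferon were the 2 lists called with the block (adjusted p = 0.0131 each). Limma called 0 genes without the block when any 1 of 10 libraries was left out and 2 without NHEK shSC replicate 1 or NHEK shKMT2D replicate 3, against 691 at an unadjusted p under 0.05 with all 12. The paired total of 426 was 202 without NHEK pair 2, 119 without NHEK pair 3 and 108 without HaCaT pair 3.

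The control libraries of HaCaT and NHEK were compared to describe the background on which each knockdown acted. HaCaT shSC had more RNA of KRT81, a hair keratin (2032 ± 1235 against 0.883 ± 0.794), EEF1A2 (9.47), BMP7 (8.94) and PTGER2 (8.59), and WSCD2 was at least 886-fold higher, having 0 reads in NHEK shSC. MGST1 (−10.76), G0S2 (−10.44) and NYNRIN (−10.17) were lower in HaCaT, and MAP9 and THY1, with 0 reads in HaCaT shSC, were at least 1001-fold and 889-fold lower. Interferon genes were lower in HaCaT, with 2 of 27 higher and 24 lower (median −2.94, camera adjusted p = 7.37e-15), such as MX1 (−5.91), as were inflammatory genes (0 and 18 of 26, median −2.96, adjusted p = 1.67e-08), such as IL1A (−3.47). Cell cycle genes were higher (32 and 0 of 40, median 1.15, adjusted p = 0.00267), such as MCM2 (2.51), and so were the KMT2 genes (11 and 0 of 16, median 0.82, adjusted p = 0.0371). Lower lists were also those of hemidesmosome (1 and 13 of 17, median −1.35, adjusted p = 1.96e-05), p53 (5 and 12 of 23, −0.89, 0.00267), mesenchymal (4 and 10 of 24, −0.70, 0.00499), p63 (4 and 11 of 22, −0.77, 0.0146), cornified (4 and 10 of 23, −1.18, 0.0146), basal (2 and 8 of 14, −1.25, 0.0163) and spinous genes (2 and 6 of 13, −1.73, 0.0163). None of these 11 calls held with an estimated correlation (adjusted p = 0.618 or more). Fry, which tests each list by itself, called 13 lists. Of those named here, it called interferon (fry adjusted p = 0.000954), inflammatory, p53, hemidesmosome and KMT2 genes (0.0125 each) and basal and mesenchymal genes (0.0235 each). It did not call cell cycle (0.113), p63 (0.106), spinous (0.117) or cornified genes (0.223). Across all 14044 genes, 5374 were higher and 2675 lower in HaCaT. The median log2 difference of all genes was 0.29, and with TMM factors on top the counts were 3881 and 3820, and list medians stand against that median.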

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

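Of the tests in this part, that of 1 factor per library and those of the lists over the exchanges within pairs were chosen only after the result was seen. The scaling test of the list medians was run again in a corrected form, because the earlier form took each fold change relative to the median of all genes and so could not respond to 1 factor per library; both forms gave 0 sign changes.

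The effect of shKMT2D differed between NHEK and HaCaT, by a test of the difference itself without the pair block, for ABCC3 (1.46, HaCaT minus NHEK, log2) and TM9SF4 (−1.32). It also differed, with camera at a preset correlation, for 6 lists, given here with their median differences, which camera does not test. These were cell cycle genes (0.54), p53 targets (−0.28), interferon response (−0.96), Wnt pathway (0.31), cholesterol synthesis (0.13) and hypoxia and glycolysis (−0.19). None of the 6 list calls held with an estimated correlation (adjusted p = 0.664, 0.351, 0.272, 0.307, 0.307 and 0.272 in that order). With the block the p53 (0 up and 0 down of 23, 0 and 3 adjusted over the list alone), Wnt (2 and 0 of 24, 2 and 0 adjusted over the list alone), cholesterol (1 and 0 of 24, 3 and 0 adjusted over the list alone) and hypoxia lists (0 and 3 of 24, 0 and 6 adjusted over the list alone) were called again (adjusted p = 0.0108, 0.0221, 0.0254 and 0.00229; 0.362 each with an estimated correlation). Among their members were TCF7L1 (1.22), WNT10B (2.26), HMGCS1 (0.82), SLC2A1 (−0.87) and SLC2A3 (−1.58). When each of the 12 libraries was left out without the block, the hypoxia list kept its call in 11 cases, p53 in 10, Wnt in 8 and cholesterol in 5, while cell cycle and interferon kept theirs in 12. When each of the 6 pairs was left out with the block, p53 lost its call without HaCaT pair 3 (adjusted p = 0.0574), Wnt without HaCaT pair 1 (0.106), and cholesterol without NHEK pair 2, HaCaT pair 1 or HaCaT pair 2 (up to 0.112). Hypoxia, cell cycle and interferon kept theirs in 6 of 6.

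The cell cycle and interferon lists moved apart in NHEK and HaCaT. The authors' scaling is argued against, since 1 factor per library moves all genes alike and yet the 2 lists moved in opposite directions in 6 of 6 pairs, while the 0 of 8 medians that changed sign under TMM factors or quantile normalization say little, as these moved the medians by 0.00982 and 0.0537 at most. Depth stays open. In NHEK, 0 of 2 medians changed sign in the pair whose shKMT2D library was the deeper one, but its depth was only 1.09 times that of shSC. In HaCaT this ratio was 0.899, 1.04 and 1.17 in pairs 1 to 3. Relative to all genes, the medians there grew in size with it, to 0.298 for cell cycle and −0.541 for interferon in pair 3. In NHEK the cell cycle median went the other way, falling as the ratio rose (−0.288, −0.416 and −0.446). That of interferon followed no order (0.639, 0.339 and 0.503). The ratios of NHEK pair 2 (0.929) and HaCaT pair 1 (0.899) were close. Yet the medians were −0.416 and 0.0782 for cell cycle and 0.339 and −0.221 for interferon. For these 2 lists, this argues against a depth effect alike in both cell types. An effect of depth that differs between the cell types was not tested. Nor did 1 pair decide the direction, since each list median had the same sign in every pair of its cell type. The 0 of 12 medians, each without 1 pair, that changed sign add little, since these like signs left hardly any room for a change. The difference between primary and immortal cells may underlie the pattern. It is confounded with all else that differs between NHEK and HaCaT and was not tested apart from it. Chance also stays open, as set out below.

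For genes, 10 of 100 drawn splits, the real one among them, gave as many as the 2 of the real split, so chance is not excluded. Relabelling within the cell types stands for no effect in either, not for an equal effect in both. Some drawn splits also kept or turned all labels of 1 cell type and so carried its whole contrast. The share therefore cannot by itself test a difference between the effects. Exchanges within pairs share this limit. The split with the most, 65, kept the labels of 4 of 6 libraries in each cell type and parted 1 pair in each. A count so far above the real one could come from a structure of the samples, which no test here looked for, and the parting of the pairs alone does not account for it, since 29 other drawn splits that parted 1 pair in each cell type gave 3 genes at most. With the block 2 of 32 exchanges within pairs gave as many as 426, the real one and that with 1418, in which the HaCaT labels are turned and the contrast becomes the sum of both effects. The other 30 exchanges gave 25 genes at most.

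For lists, 45 of 100 drawn splits, the real one among them, gave as many as the 6 of the real split (13 at most in the others), but these splits ignore the pairs and count any list. Over the 32 exchanges within pairs, 4 measures were run. As many lists as the real 7 were called by camera in 12 exchanges (highest other 12), and as many as the real 2 by fry in 2 (highest other 2), so chance is not excluded for the number of lists. The smallest p of any list, that of cell cycle, was reached in 1 exchange, the real one (30.4 as −log10 p, highest other 27.4). The distance between the cell cycle and interferon medians was also largest in the real one (1.39 in the highest other), but these lists were picked for that distance. A share of 1 in 32 is under 0.05 by itself, but it was found among these 4 and 7 measures in all, so chance was not taken as excluded for the pattern.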

How the results depend on the processing

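The deposited values plus 1, voom, the sign-flip test of KMT2D in both its forms and the paired fits' own alternatives were chosen only after the result was seen; the other settings were planned. The planned tests with edgeR and DESeq2 were not run. The control comparison has no block.

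KMT2D kept its direction under every setting that was run. With the block its log2 fold change of −0.42 (−0.418) in NHEK passed the threshold, and over both cell types an exact sign-flip test gave p = 0.0312, or 0.0625 with the sign of HaCaT pair 3 turned, where KMT2D differed within counting error. In number of genes, the calls without the block changed most with the block itself, from 0 to 1408 genes in NHEK, from 78 to 485 in HaCaT, from 2 to 426 for the difference of effects and from 0 to 119 for shared genes. By ratio the 78 in HaCaT changed more without HaCaT shSC replicate 2, to 1. In 1 fit on all 12 libraries NHEK had 5 genes, HaCaT 10 and both 1. In HaCaT the deposited values plus 1 gave 43 genes and 2-fold calls alone 42, and between the controls 2-fold calls gave 4785. The fold change correlation was 0.197 with no filter. With the block, the deposited values plus 1 gave 169 genes in HaCaT and 43 shared, and 2-fold calls alone gave 247 in NHEK, 153 in HaCaT, 167 for the difference and 18 shared. The fall under 2-fold calls follows from the stricter limit, and the cause of the other changes was not tested.

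List calls in NHEK, in HaCaT and for the difference rested on the preset correlation. With an estimated correlation 0 lists were called in NHEK, 0 in HaCaT and 0 for the difference, with and without the block. With fry 0 were called in each, except 2 for the difference with the block, cell cycle and interferon. A filter of 50 ended the spinous and cornified calls in HaCaT with and without the block, that of transcription factors with it and the Wnt call in NHEK without it. The deposited values plus 1 ended that of transcription factors in HaCaT (0.057) and of Wnt for the difference (0.0706) with the block, and of Wnt for the difference (0.0736), desmosome (0.0562) and p53 genes (0.051) in NHEK without it. Without the block no filter ended desmosome, p53 and Wnt calls in NHEK and Wnt for the difference, quantile normalization desmosome in NHEK and cholesterol for the difference, and voom desmosome in NHEK.

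Without each library in turn, the counts ran from 0 to 0 in NHEK, 1 to 22 in HaCaT, 0 to 2 for the difference, 0 to 0 for shared genes and 5645 to 8510 between the controls. The correlation ran from 0.206 to 0.293. Lists ran from 1 to 10 in NHEK, 2 to 7 in HaCaT and 5 to 8 for the difference. KMT2D ran from −0.66 to −0.20 in NHEK and from −0.85 to −0.24 in HaCaT. Without each pair in turn, the paired counts ran from 329 to 1210 in NHEK, 59 to 1035 in HaCaT, 108 to 427 for the difference and 26 to 207 for shared genes. Paired lists ran from 9 to 11 in NHEK, 4 to 13 in HaCaT and 5 to 8 for the difference. These fits keep 2 pairs and lean on the spread that limma pools over genes. On simulated reads the paired fits called 18 unchanged genes among 202 in NHEK and 11 among 197 in HaCaT. The cause of these changes was not tested beyond there being fewer libraries.

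For the 235 gene values named in the text, 3116 alternatives were computed. Of these 2697 kept the direction and the side of the threshold, 390 lost the call, 29 gained one and 0 turned the direction. In all, 90 of the values kept both under every alternative that was run. Genes with 0 or few reads in a group, such as CLDN11 and GPX3 in HaCaT, are limited by depth.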

Other observations

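Of the tests in this part, that of exchanged libraries in HaCaT pair 3 and that of groups of genes by level were chosen only after the result was seen.

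Inflammatory genes went both ways in NHEK and HaCaT. In NHEK, 5 of 29 rose and 6 fell by the paired fit (6 and 7 adjusted over the list alone; median −0.20, camera adjusted p = 0.848), with IL33, PTGS2 and S100A8 up and TNF and SAA1 down. In HaCaT, 1 of 18 rose and 4 fell (2 and 5 adjusted over the list alone; median −0.12, adjusted p = 0.344), with IL1A (−0.69), IL1B (−0.62), ICAM1 (−0.95) and PTGS2 (−0.84) down. Of 24 mesenchymal genes, 0 rose and 4 fell in NHEK (0 and 4 adjusted over the list alone; median 0.03, adjusted p = 0.707), among them TNC (−0.86) and COL4A2 (−0.63), and 1 rose and 2 fell in HaCaT (3 and 3 adjusted over the list alone; median 0.04, adjusted p = 0.666), TWIST1 at 1.43, SPARC at −1.54 and LOX at −0.84. Of 19 lipoxygenase and ferroptosis genes in NHEK, 3 rose and 0 fell (3 and 0 adjusted over the list alone; median 0.01, adjusted p = 0.707), the ferritin genes FTL (0.39) and FTH1 (0.36) and the transferrin receptor gene TFRC (0.36). In HaCaT, 1 of 18 rose, TFRC at 0.62, and 0 fell (1 and 0 adjusted over the list alone; median −0.13, adjusted p = 0.26).

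Within NHEK and within HaCaT, signaling lists were not called with the block, apart from Notch in HaCaT. Of 22 Wnt genes in NHEK, 1 rose and 3 fell (1 and 3 adjusted over the list alone; median −0.12, camera adjusted p = 0.0734), SFRP1 at 0.58 and WNT7A (−0.50), WNT10A and WNT10B (−1.55) lower, and of 24 in HaCaT, 2 rose and 1 fell (3 and 1 adjusted over the list alone; median 0.02, adjusted p = 0.359), FZD7 at 0.63, TCF7L1 at 1.23 and WNT7A at −1.03. LTBP2 fell in both (−0.78 and −0.88) within a TGF-beta and BMP list of 20 in NHEK (0 and 4, and 0 and 4 adjusted over the list alone; median 0.07, adjusted p = 0.804) and 23 in HaCaT (0 and 1, and 2 and 1 adjusted over the list alone; median 0.15, adjusted p = 0.359). EREG (0.95 and 0.93) and ERRFI1 (0.41 and 0.52) rose in both within 18 EGFR genes (2 and 2 in NHEK, 2 and 2 adjusted over the list alone, median −0.04, adjusted p = 0.967; 2 and 0 in HaCaT, 2 and 0 adjusted over the list alone, median −0.03, adjusted p = 0.654). The median and mean of a list differed in sign for EGFR and immediate early genes in NHEK and for inflammatory, mesenchymal and EGFR genes in HaCaT, none of them called. Of 14 Notch genes in NHEK, HES4 rose (1.16) and JAG2 fell (1 and 1 adjusted over the list alone; median 0.03, adjusted p = 0.967). Of 18 immediate early genes in NHEK, 4 rose and 1 fell (4 and 1 adjusted over the list alone; median −0.03, adjusted p = 0.44), with EGR3 (1.28), DUSP1 (1.11) and JUN (0.42) up and IER3 (−0.64) down, and of 19 in HaCaT 0 and 0 (0 and 0 adjusted over the list alone; median 0.14, adjusted p = 0.219).

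KMT2D hardly differed within HaCaT pair 3. An exchange of its libraries is argued against by the fold changes of pair 3, which correlated with the mean of pairs 1 and 2 at r = 0.592 across genes. A loss of long transcripts in its shSC library is argued against by the 1395 longest genes, which lay at a median log2 difference of −0.08 (−0.0811) from the other shSC libraries, where KMT2D lay at −1.18. Counting noise is argued against by the 95% exact bounds of 92.8% and 105%, against a mean of 62.6% in pairs 1 and 2. No biological explanation was tested.

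More genes were higher in HaCaT than in NHEK controls. With the median of all genes set to 0, the share of calls that were higher went from 66.8% to 49.1%, so the scaling between the cell types may make the excess, though centring would remove a real broad difference equally. Whether 1 factor moved every gene alike cannot be told apart from a difference that follows level. Of 10 equal groups of genes by level, 2 had a median over 0.15 away from that of all genes (0.29), those with the lowest levels. The next group above these lay at 0.411, and the 2 groups with the highest levels lay at 0.14 and 0.15, all within that limit. Departures over the limit were thus confined to the 2 groups with the lowest levels, while smaller ones were also seen at the highest levels.

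For the other comparisons, 3 against 3 libraries make 10 splits and 3 pairs make 4 exchanges, too few for a share under 0.05. In NHEK, 10 of 10 splits gave as many genes as the real value of 0 (highest other 0), 2 of 10 as many lists as 11 (highest other 11, in a split that parts 1 pair, while those that part 3 pairs gave 6 at most), and 1 of 4 exchanges as many genes as 1408 (highest other 0). In HaCaT, these were 1 of 10 for 78 genes (highest other 1), 8 of 10 for 5 lists (highest other 10) and 1 of 4 for 485 genes (highest other 0). Between the controls they were 1 of 10 for 8049 genes (highest other 0). With the block, camera called 10 lists in NHEK, against 4, 8 and 6 in the other exchanges. In HaCaT it called 7, against 5, 7 and 5, so exchanged labels gave as many lists there. Over 32 exchanges within the pairs of both cell types, the correlation of 0.281 was reached in the real one alone (1 exchange, highest other 0.218). That share is under 0.05 by itself, but it belongs to 1 of 7 measures run over these exchanges, so chance was not taken as excluded. The 119 genes changed the same way were also reached in the real one alone (highest other 26), but 30 exchanges had 0 genes called in at least 1 cell type, which fixes the shared count at 0, and the 2 that are left are too few for a share under 0.05.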
